A study of Mus musculus with 6 samples.

How the data were processed

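DNA of 6 lymphomas, described as Lck-Cre conditional knockouts of Hdac1 and Hdac2, and tail DNA were labelled with different dyes and hybridised to NimbleGen whole-genome arrays, per the labels' protocols. The labels place the tumours in 3 genotype groups with 1, 1 and 4 tumours, and they carry no replicate numbers. They describe each tail DNA as that of mice of the same genotype and call it matched. They do not state that the 4 tumours came from separate animals, so that the limma p-values given below measure the spread between these 4 samples. The permutation tests measure no such spread and take the tumours as independent, which the labels do not state. The arrays lay on 3 slides: slide 1 held the Hdac1L/L and Hdac1L/+;Hdac2L/L tumours, slide 2 tumours 1 to 3 and slide 3 tumour 4.

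Per the file headers, the authors deposited for each array the log2 intensity of each channel, an uncorrected log2 ratio, and a corrected log2 ratio after a spatial correction and a normalization between channels. Their methods and software versions are not given in the sources used here. The corrected ratio is EXP minus REF, and the series table holds the same log2 values as the deposited per-array files, with a largest difference of 0 and column medians from -0.02 to -0.002. Its scale, direction and lack of centring are therefore those of the array files. Median log2 intensities ranged from 10.8 to 11.9 in the EXP channel and from 11.5 to 12.4 in the REF channel. The authors deposited segment means on the log2 scale for 5 arrays, with segMNT named for 4 of them and DNACopy for tumour 4 by the file names. A segment table of the Hdac1L/L tumour was not used here. The G and C fraction of each probe was taken as deposited, per the file headers.

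Probe coordinates were used as the files give them. The headers give chromosome 1 a length of 197195432, that of mouse build NCBI37 (mm9). The gene table at hand, of assembly GRCm38.p6, is of another build, so it served only for gene names and chromosomes, for which all 112 entries of the gene lists matched. For the same reason Hdac1, Hdac2, Jdp2 and the other listed genes were not placed on the probes. The ratios at Hdac1 and Hdac2 were not analysed, and no check of the labels was made from them. In place of the T cell receptor loci, the windows that overlap a called loss in all 6 tumours were described.

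Each array's corrected log2 ratios were centred on the median of its autosomal probes. Medians were taken in 1 Mb bins (2417 autosomal bins, with a median of 54 probes), and the median of an autosome's bins was called gained above 0.15 and lost below -0.15. Its 95% interval came from 1000 resamples of bins in blocks of 5 and covers the spread along the chromosome, not that between tumours. Recurrence of whole-chromosome gains was tested with 100000 placements of each tumour's calls on random autosomes. Focal segments came from a recursive binary segmentation per chromosome with a split statistic above 6 in units of the array's noise and at least 5 probes. They were called where the median lay beyond 0.2 on either side of 0 and the segment spanned under 50% of its chromosome. Shared 100 kb windows were tested by shifting each tumour's calls around the autosomes 10000 times. Bins were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, Benjamini-Hochberg, adjusted p under 0.05), for the 4 tumours against 0 and for each lone tumour against the 4. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

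The methods were tested on simulated data. For the segmentation, planted segments of 5 probes at -0.6 were found in 94.9% and those at 0.35 in 34.5% of cases. The rates were 100% and 78.6% with 10 probes and 100% for both with 50 probes. Arrays differed: at 0.35, segments of 5 probes were found in 0% of cases on both slide 1 arrays and in 94.1% on that of tumour 2. Segments of 10 probes at 0.35 were found in 31.6% on the Hdac1L/L array, in 50% on the Hdac1L/+;Hdac2L/L array and in 100% on the others. With 128498 autosomal probes per array, 0 false segments were called over 6 arrays. For the 4 tumours against 0, limma found 87% of planted bins at -0.2 and 100% at 0.35 among 2417 bins, with 6 false calls. For the Hdac1L/L tumour against the 4, it found 64% at -0.35 and 99% at 0.6, with 10 false calls. These simulations drew independent probes or bins and leave out trends along the genome and the block-wise rise of probe scatter on 2 arrays. The false calls on the real arrays may therefore be more frequent.

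Results named in the text followed a rule fixed before the data were examined: every whole-autosome call, the 5 called focal segments with the largest absolute median per tumour, and every region called in the same direction in 3 or more tumours. Listed genes inside called focal segments were not named, because the genes were not placed. Some segments and list members that this rule or the gene lists would name are not reported here. Alternatives fixed at the same time were other call thresholds, centrings, bin sizes and summaries, the series table, stricter segmentation, the authors' segments, windows of 1 Mb, the slide as a random block, and leaving out each of the 4 tumours in turn. Alternatives chosen after seeing the data were slide 1 ratios turned, uncorrected ratios, bins corrected for GC content, segments called relative to whole gained chromosomes and joined, and counts without the 2 arrays with block-wise scatter. With no second group of 3 or more tumours, no other split of the samples could be compared.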

Results

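DNA copy number was measured in 6 mouse lymphomas that the labels describe as conditional knockouts of Hdac1 and Hdac2, with a Cre transgene under the T cell promoter Lck. Both genes encode histone deacetylases that act in the same corepressor complexes. Each lymphoma was hybridised with normal tail DNA labelled as matched to it on 1 array of 137221 probes, 128498 of them on autosomes, with a median distance of 18.5 kb between probes of chromosome 1. The labels place 1 tumour in the genotype Hdac1L/L, with Hdac2+/+, 1 in Hdac1L/+;Hdac2L/L and 4 in Hdac1L/L;Hdac2L/+, with L written as in the labels, which do not define it. The 4 are called tumours 1 to 4 here, and the numbers only name them. All animals had a mixed FVB and C57 background. Probe noise, as the SD of a log2 ratio judged from neighbouring probes, was 0.20 and 0.19 for the Hdac1L/L and Hdac1L/+;Hdac2L/L tumours. It was 0.13, 0.11, 0.14 and 0.13 for tumours 1 to 4. The number of arrays limits the precision of every comparison, and the 2 lone tumours have no replicate.

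A log2 ratio above 0 stands for more DNA in the EXP channel than in the REF channel of the file headers, after centring on the autosomal median. For tumours 1 to 4 the headers and the dyes in the labels both make this tumour over tail. For the Hdac1L/L and Hdac1L/+;Hdac2L/L tumours, which share slide 1, the headers put EXP in the channel of the dye that the labels give to the tail. Tumour over tail is therefore only the likely direction on slide 1. It rests on the EXP and REF headings and on losses at loci shared with the other tumours. Every gain of these 2 tumours would be a loss, and every loss a gain, if the dyes of the labels held.

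Chromosome 15 was gained in 6 of 6 lymphomas, with 99.0% of its 1 Mb bins above 0.15 in tumour 1 and 100% in the others. Its first 41 probes in tumour 1, up to 3741862, were at -0.10, and its first 8 in tumour 3, up to 3129013, at -0.08. In the 4 Hdac1L/L;Hdac2L/+ tumours its median log2 ratio was 0.38 ± 0.02 (SD, n = 4), with single values of 0.37, 0.41, 0.38 and 0.35 for tumours 1 to 4. The Hdac1L/L tumour had 0.36 (95% interval over bins 0.34 to 0.39, or -0.36 with the sign turned) and the Hdac1L/+;Hdac2L/L tumour 0.37 (0.35 to 0.37, or -0.37 with the sign turned). Chromosome 15 carries Myc, the oncogene named with its collaborating genes in the title of the series, and Pim3, a kinase of the Pim family that cooperates with Myc. It also carries Il7r, the interleukin 7 receptor of developing lymphocytes, and the deacetylase genes Hdac7 and Hdac10. None of these genes was placed on the probes.

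Each tumour's whole-chromosome gains were placed on random autosomes to test how often 1 autosome is shared by chance. Sharing by 6 of 6 tumours gave p = 1e-05 in a one-sided permutation test, the smallest value that 100000 resamples can give. Among the 4 Hdac1L/L;Hdac2L/+ tumours alone, 4 of 4 gave p = 0.00071 in the same permutation test. A sign-flip test of the chromosome 15 median of these 4 tumours gave an exact two-sided p of 0.125, the smallest that 4 tumours allow. With the slide 1 ratios turned, 4 tumours had a gain and 2 a loss of chromosome 15, and the permutation p for 4 of 6 gains was 0.0005.

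**Figure D1:**
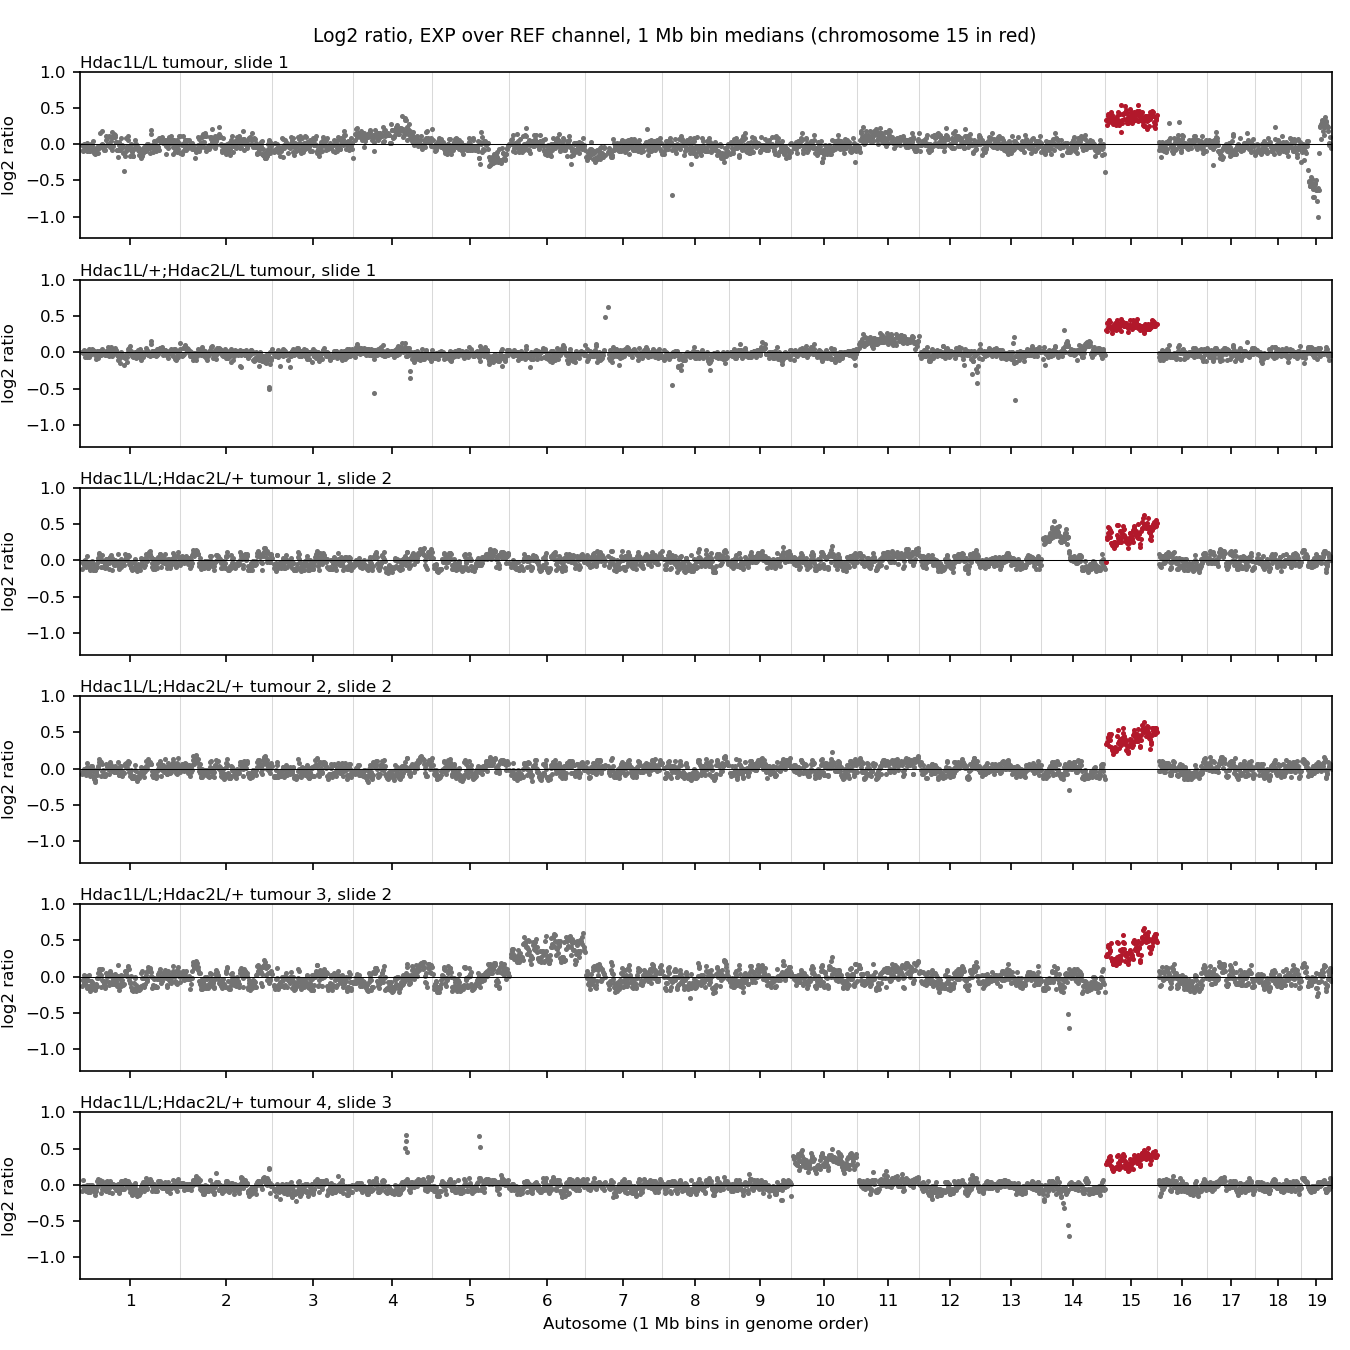
Median log2 ratio of EXP over REF (vertical axis) in each 1 Mb bin of the autosomes in genome order (horizontal axis), with 1 panel per tumour and chromosome 15 in red. Chromosome 15 lies above 0 in all 6 panels, at medians from 0.35 to 0.41, while gains of chromosomes 6, 10 and 11 and of part of chromosome 14 appear in 1 panel each. On slide 1 the direction is the likely one.

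Apart from chromosome 15, whole-autosome gains differed between tumours. Tumour 3 gained chromosome 6, at a median log2 ratio of 0.36 (95% interval over bins 0.30 to 0.41), and tumour 4 gained chromosome 10, at 0.32 (0.29 to 0.35). The Hdac1L/+;Hdac2L/L tumour had a lower gain of chromosome 11, at 0.154 (0.14 to 0.17, or -0.154 with the sign turned), just above the call threshold of 0.15, with 54.6% of its bins above that level. That call ended at a threshold of 0.25 and with uncorrected ratios, where the median was 0.148. In all, 9 gains and 0 losses were called among 114 pairs of autosome and tumour, or 6 gains and 3 losses with the slide 1 ratios turned. The other 105 medians ranged from -0.07 to 0.12, where 0.12 was chromosome 4 of the Hdac1L/L tumour (-0.12 with the sign turned).

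The 4 gained autosomes were set against the gene lists fixed before the data were examined, using the chromosome given for each gene by the annotation GRCm38.p6. Of 25 Myc and Myc collaborating genes, 2 lie on chromosome 15, namely Myc and Pim3, and none on chromosome 11. Chromosome 6 carries Ccnd2, a cyclin of the G1 phase, and chromosome 10 carries Ahi1 and Myb, a transcription factor of early lymphoid cells. Of 20 genes of the p53 pathway, none lies on chromosome 15, whereas Mdm2, which turns p53 over, and Apaf1 lie on chromosome 10, Cdkn1b on chromosome 6 and Trp53 itself on chromosome 11. Hdac2, 1 of the 2 targeted genes, is on chromosome 10, gained in tumour 4 of the genotype Hdac1L/L;Hdac2L/+. Of 36 T cell leukaemia genes, 6 lie on chromosome 11, among them Ikzf1 and Ikzf3, lymphoid zinc finger factors, and Tcf7. Ezh2 and Etv6 lie on chromosome 6 and Il7r on chromosome 15, and none lies on chromosome 10. Of 29 genes of HDAC1/2 complexes and other deacetylases, 3 lie on chromosome 11 (Chd3, Hdac5 and Ncor1), 2 on chromosome 6 (Chd4 and Hdac11) and 1 on chromosome 10 (Mbd3). These counts describe chromosomes and were not tested, since 1 gain carries all genes of its chromosome together.

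**Figure D2:**
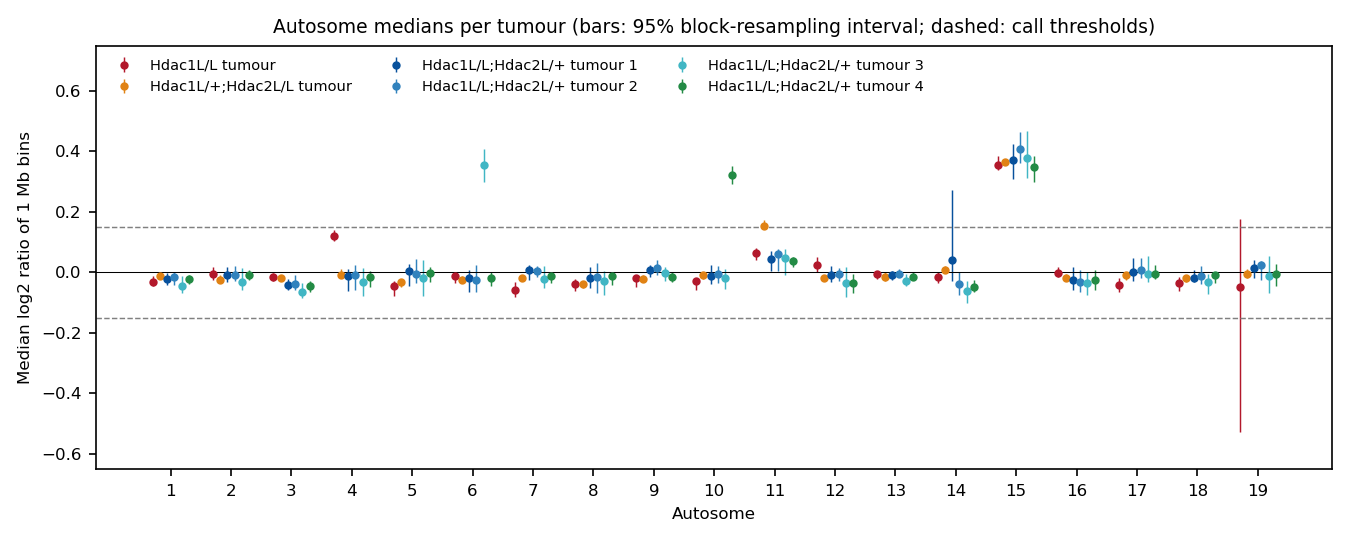
Median log2 ratio of the 1 Mb bins of each autosome (vertical axis) by autosome (horizontal axis) for the 6 tumours, with 95% intervals from resampling bins in blocks as bars and the call thresholds of 0.15 and -0.15 as dashed lines. Chromosome 15 is above the upper line in 6 tumours, and chromosomes 6, 10 and 11 in 1 tumour each. The wide bars on chromosomes 14 (tumour 1) and 19 (Hdac1L/L tumour) belong to chromosomes changed over part of their length.

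Short losses on chromosomes 6 and 14 were called in all 6 lymphomas at the main settings. On chromosome 6, the windows from 41100001 to 41500000 (coordinates of the array files, whose chromosome 1 length equals that of mouse build NCBI37) each overlapped a called loss in every tumour. The median of their 21 probes was -0.54 ± 0.02 (SD, n = 4) in the 4 Hdac1L/L;Hdac2L/+ tumours, -1.55 in the Hdac1L/+;Hdac2L/L tumour and -0.39 in the Hdac1L/L tumour (1.55 and 0.39 with the sign turned). In tumour 3, where the rest of chromosome 6 was gained, the windows were at -0.91 relative to a flank at 0.37. On chromosome 14, the windows from 54500001 to 54800000 with 16 probes had medians of -1.84, -0.60, -2.18 and -1.12 in tumours 1 to 4, with a mean of -1.44 ± 0.71 (SD, n = 4). They had -1.43 in the Hdac1L/L tumour and -0.38 in the Hdac1L/+;Hdac2L/L tumour (1.43 and 0.38 with the sign turned). Part of these windows was called a gain in the Hdac1L/+;Hdac2L/L tumour, at 0.455 from 54524011 to 54599251, next to its losses at -0.34 from 54413156 to 54506285 and -0.58 from 54618436 to 54784101. At -2.18, the EXP channel held 22.1% of the DNA level of the REF channel. The T cell receptor beta locus is known to lie on mouse chromosome 6 and the alpha and delta loci on chromosome 14, and these loci lose DNA when they rearrange in T cells. Whether the lost windows hold these loci was not checked against an annotation of this build.

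**Figure D3:**
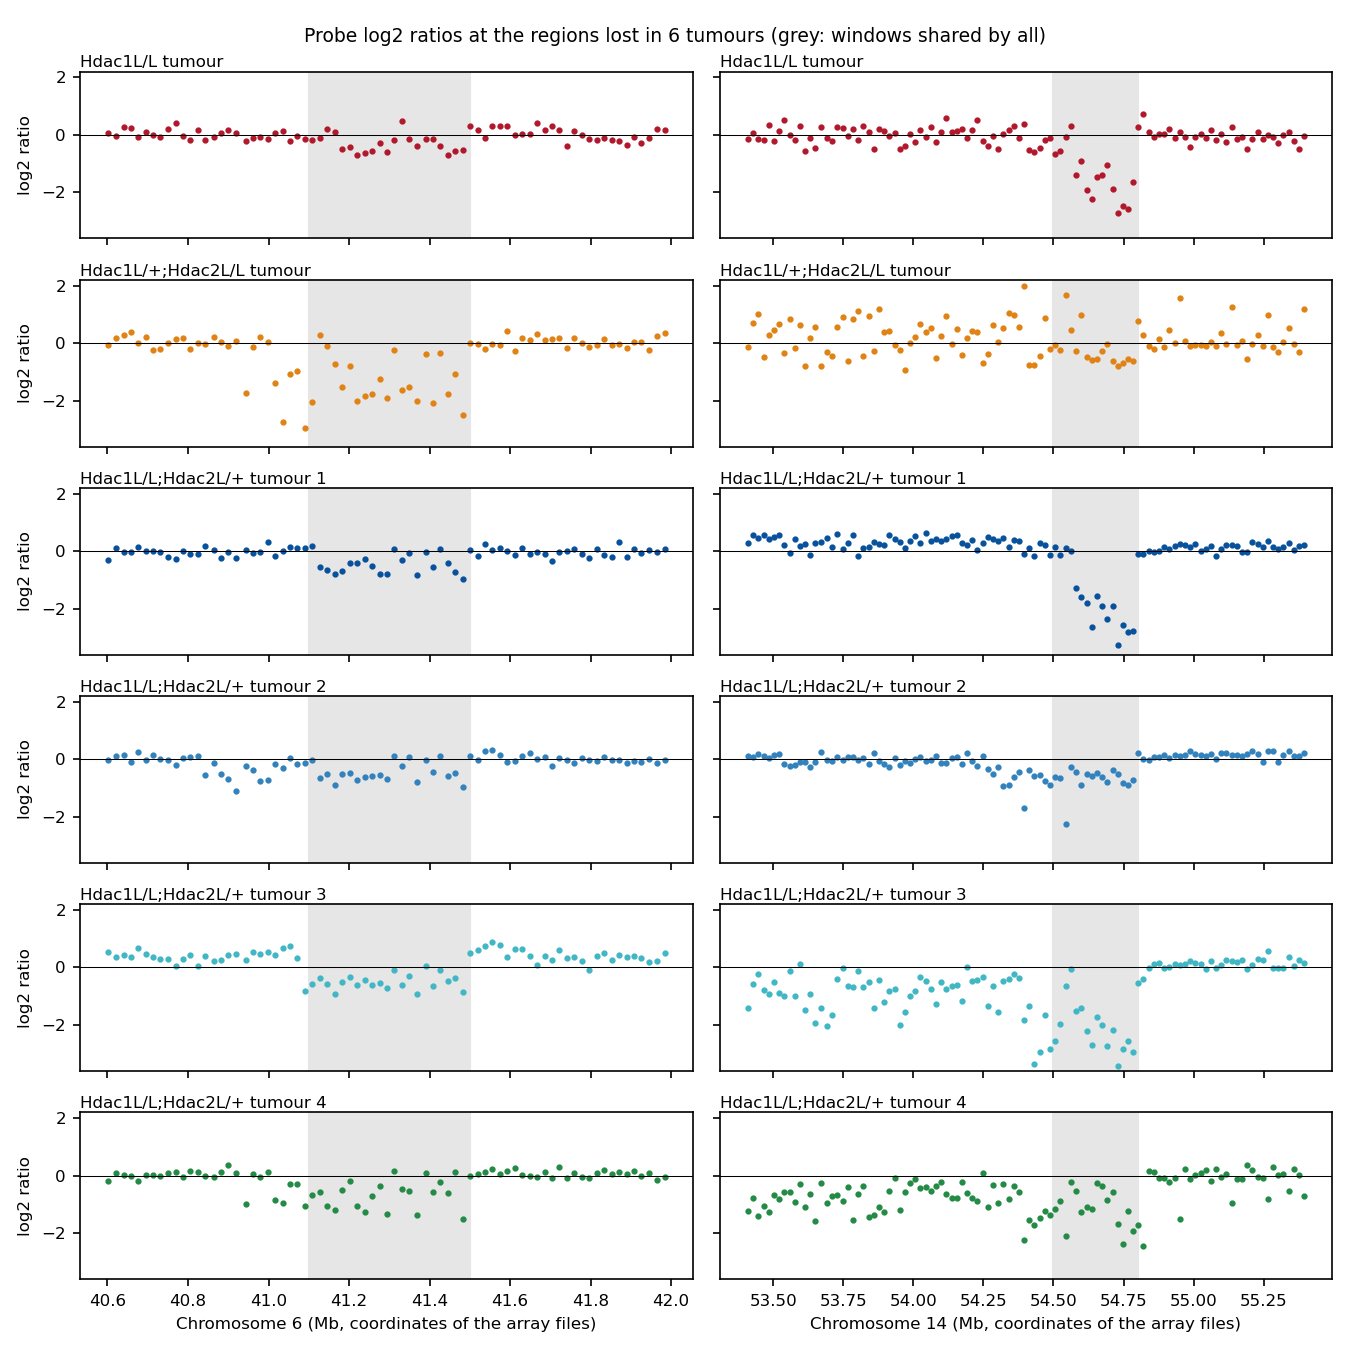
Log2 ratio of single probes (vertical axis) along chromosome 6 (left) and chromosome 14 (right) in Mb (horizontal axis), with 1 row per tumour and the windows that overlap a called loss in all 6 tumours in grey. In the grey windows medians range from -0.39 to -1.55 on chromosome 6 and from -0.38 to -2.18 on chromosome 14.

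Calls in 6 of 6 tumours on 1 window of 100 kb exceeded what shifted calls gave, with p = 0.0002 in a one-sided permutation test of 10000 resamples. With the slide 1 ratios turned, the most was 5 tumours (permutation p = 0.006). With a split statistic above 8 and with uncorrected ratios, only chromosome 14 had a window called in 6 tumours, and with the authors' segments only chromosome 6 had one called on all 5 arrays. The total of 1224 windows shared by 2 or more tumours did not exceed shifted calls, which had a median of 1211 (permutation p = 0.49). This total counts a window once, whether 2 or 6 tumours share it, and includes segments of whole gained chromosomes. It therefore cannot decide whether focal changes were shared. Of the shared windows, 1005 were gains on chromosome 15. With segments called relative to whole gained chromosomes and joined, a setting chosen after seeing the data, 226 windows were shared against 77 in shifted calls (permutation p = 0.01), and the authors' deposited segments of 5 arrays gave 1129 against 252 (permutation p = 0.033). Besides both windows and chromosome 15, only 2 regions were called in the same direction in 3 tumours. The first was a loss from 47600001 to 47800000 on chromosome 6, with -0.68 and -0.67 in the Hdac1L/L and Hdac1L/+;Hdac2L/L tumours and -0.31 in tumour 4, against 0.03, 0.05 and 0.47 in tumours 1 to 3. With the slide 1 ratios turned, this loss would remain in tumour 4 alone. On the 2 arrays with block-wise scatter, the same 5 probes from 47613742 to 47725524 were called. Their 5 Mb window had a scatter of 0.33 on the Hdac1L/+;Hdac2L/L array, against a median of 0.20, and 0.18 against 0.14 in tumour 4. Whether this region is a copy number loss was not tested. The second was a loss from 53600001 to 53800000 on chromosome 14, with -1.16 in tumour 3 and -0.80 in tumour 4. The Hdac1L/+;Hdac2L/L tumour had a called loss in part of it, at -0.39 from 53612857 to 53710317, but a median of -0.08 over the whole, and tumour 1 was at 0.28.

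The Hdac1L/L tumour had a long partial loss of chromosome 19. In joined segments from 14216497 to 36472844, 1199 probes over 22.3 Mb had a median log2 ratio of -0.58, or 66.9% of the REF level. From 46141474 to 54682669 on the same chromosome it was 0.28. Its deepest segment of all was on chromosome 14, at -2.46 from 54710880 to 54784101. With the sign turned, these losses would be gains of up to 2.46.

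Tumour 1 gained the proximal part of chromosome 14, from 3004892 to 54376977, at a median of 0.34 over 2713 probes and 51.4 Mb of joined segments. Beyond it lay its losses from 54580556 to 54673053 at -1.69 and from 54691730 to 54784101 at -2.67, with 6 probes each. Its other large segments were a loss on chromosome 6 from 41127327 to 41294464 at -0.60 and parts of the gained chromosome 15 at 0.61. Tumour 3 had its deepest segments in the same part of chromosome 14, at -2.54 from 54394783 to 54506285, -2.39 from 54618436 to 54821225, -1.40 from 54524011 to 54599251, -1.56 from 53612857 to 53710317 and -1.10 from 53858543 to 53988469. Tumour 4 had -1.83 from 54729058 to 54821225, -1.49 from 54394783 to 54543168 and -1.26 from 53784809 to 53895277 on chromosome 14, and on chromosome X -1.63 from 122152833 to 122229423 and -1.62 from 121841974 to 121937338. The chromosome X segments had 5 and 6 probes with interquartile ranges of 1.22 and 1.31, against a noise SD of 0.13 on this array. Their probes thus did not shift evenly, and whether they are copy number losses was not tested. Tumour 4 also had segments above 0 on chromosome 4 from 103277440 to 106524574 at 0.63 and on chromosome 5 from 93439384 to 96226015 at 0.54. They were not among its 5 largest and were chosen after their values were seen. The chromosome 5 segment lay in 5 Mb windows of high probe scatter on this array, at 0.32 and 0.28 against a median of 0.14. Whether it is a copy number gain was not tested. The largest changes of tumour 2 were losses on chromosome 14 from 54321092 to 54394783 at -0.89 and from 54413156 to 54543168 at -0.63 and on chromosome 6 from 41127327 to 41294464 at -0.61. Its other large segments, at 0.67 and 0.58, were parts of the gained chromosome 15.

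The Hdac1L/+;Hdac2L/L tumour had its lowest segment medians on chromosome 6, at -1.86 from 41220114 to 41294464, -1.73 from 41016587 to 41109180 and -1.58 from 41312390 to 41482217. It further had -1.70 from 36236094 to 36310798 on chromosome 16 and -1.26 from 120758360 to 120832458 on chromosome 2. With the sign turned, these medians would be 1.26 to 1.86. The chromosome 2 segment had 5 probes with an interquartile range of 0.91. It lay in a 5 Mb window of high probe scatter on this array, at 0.45 against a median of 0.20. Whether it is a copy number change was not tested. The chromosome 16 segment was also called in tumour 4, there above 0 at 1.075. In total, 769 focal segments were called, 466 above and 303 below 0, of which 267, of either sign, lay on whole gained chromosomes. With the slide 1 ratios turned, 547 were above and 222 below 0. The Hdac1L/+;Hdac2L/L tumour with 194 and tumour 4 with 283 held most of them, and on both arrays the scatter of single probes rose in blocks along the genome. Without these 2 arrays, 225 segments above and 67 below 0 remained in the count, and the authors' deposited segments of 5 arrays gave 157 and 76.

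**Figure D4:**
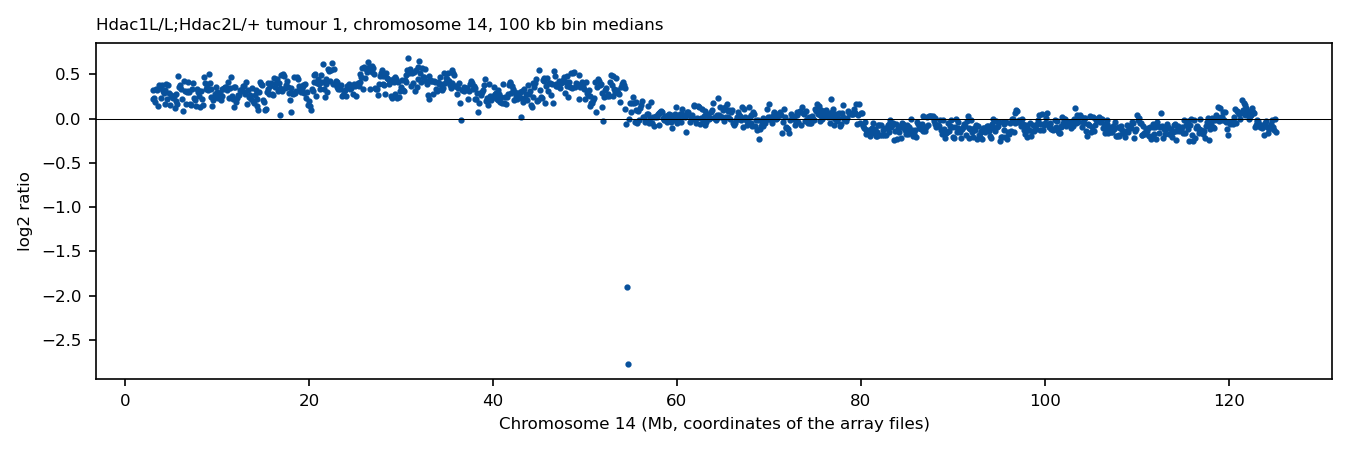
Median log2 ratio in 100 kb bins (vertical axis) along chromosome 14 of tumour 1, in Mb (horizontal axis). The gain at 0.34 ends next to a deep loss.

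The mean of the 4 Hdac1L/L;Hdac2L/+ tumours was then tested against 0 in each 1 Mb bin with limma. Chromosome 15 was higher in 101 of its 101 bins, at a median log2 of 0.37 with a median standard error of 0.02, a range of 0.19 to 0.61 and limma adjusted p-values from 0.000282 to 0.0427. Chromosome 10, gained in tumour 4 alone, had 8 called bins. Across 2417 bins, 556 were higher and 676 lower at an adjusted p under 0.05. Outside chromosome 15, the 1131 called bins had a median size of 0.09 on the log2 scale, and 22 exceeded 0.15. Without tumour 1 the counts were 291 and 456, and without tumour 2 they were 249 and 425. With the slide as a random block 412 bins were higher and 538 lower. Centring on the mode turned the split to 728 higher and 509 lower, and correction for GC content to 465 and 318. Tumours 1 to 3 share slide 2, and their bins outside chromosome 15 correlated at 0.46 to 0.72. The main test took the 4 arrays as independent. Whether the small shifts outside chromosome 15 are copy number or a trend shared by arrays was not tested.

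Against the mean of the 4, limma called the single Hdac1L/L tumour higher in 294 bins and lower in 262. In the likely direction of slide 1, the longest runs were a lower ratio on chromosome 19 and a higher one on chromosome 4. The first lay from 14000001 to 37000000 (median log2 difference -0.55, median standard error 0.03) and the second from 75000001 to 100000000 (0.27 and 0.03). Runs were not listed with the sign turned. A lower ratio also ran on chromosome 5 from 112000001 to 126000000 (-0.30 and 0.04). Part of the differences on chromosomes 4 and 5 lay in the mean of the 4, which was itself called away from 0 with the opposite sign. That mean was at 0.106 on chromosome 5 from 118000001 to 126000000 and at -0.132 on chromosome 4 from 89000001 to 94000000. On chromosome 15 the median of this tumour was 0.36, against a mean of 0.38 in the 4. With the sign turned it would be -0.36, far below the 4. The lone tumour has no spread of its own and was assumed to vary like the 4, and the counts fell to 1 higher and 17 lower without tumour 1 and to 1 and 15 without tumour 2, and they were 375 and 400 without tumour 4. Uncorrected ratios gave 155 and 132. Genotype and slide cannot be told apart in this comparison, and turning the sign gave 319 higher and 278 lower bins.

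Against the mean of the 4, limma called the single Hdac1L/+;Hdac2L/L tumour, under the same assumption on its spread, higher in 12 bins and lower in 10. The higher ones included bins on chromosome 11, with a median difference of 0.25, and on chromosome 7, at 0.55. With the sign turned, the chromosome 11 median of this tumour would be -0.154, against a mean of 0.047 in the 4. Its chromosome 15 median would then be -0.37, against 0.38. The lower ones included bins on chromosome 12 at a median of -0.40 and on chromosome 4 at -0.45. The first such bin on each chromosome lay in a 5 Mb window of high probe scatter on this array. The scatter was 0.33 on chromosome 12 from 110000001 and 0.31 on chromosome 4 from 40000001, against a median of 0.20. Whether these bins are copy number differences was not tested. In this limma contrast 749 of the 2417 bins had an unadjusted p under 0.05. The limma counts were 0 and 0 without tumour 1 and without tumour 2, where 492 and 518 bins had an unadjusted p under 0.05. They were 2 and 4 without tumour 3, and 133 and 190 without tumour 4. Slide and genotype cannot be told apart here either, and with the sign turned 169 bins were higher and 207 lower. Centring on the mode moved the split to 11 higher and 5 lower.

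**Figure D5:**
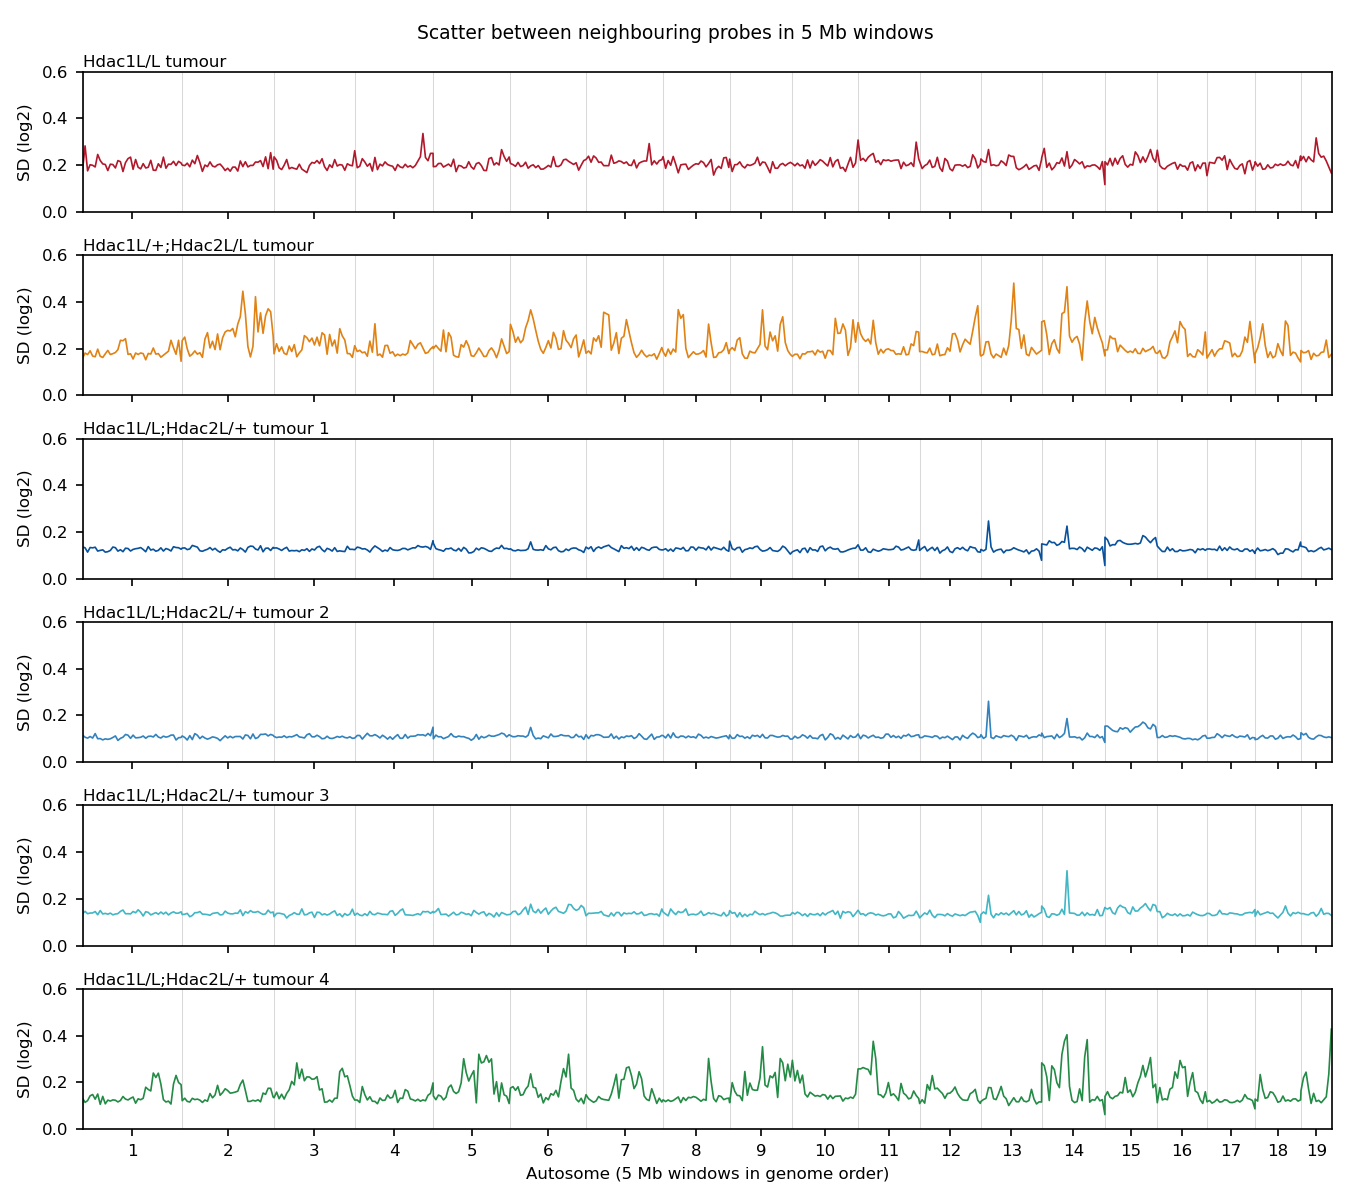
SD of the log2 ratio between neighbouring probes (vertical axis) in 5 Mb windows along the autosomes (horizontal axis), with 1 panel per tumour. The Hdac1L/+;Hdac2L/L tumour and tumour 4 show blocks of high scatter, with 12.5% and 19.4% of windows above 1.4 times their median, against at most 1.59% on the other arrays.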

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

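The tests of the direction on slide 1, of noise of each array, of somatic change, of strain make-up, of a slide 1 effect and of a full extra copy were chosen only after the results had been seen; those of loss of heterozygosity and GC content were set before their own values were seen, when the scatter and the counts of GC-corrected bins were already known.

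Among 23 measures compared within the 4 Hdac1L/L;Hdac2L/+ tumours, 4 had a tumour far from the other 3. Chance gives about 1 in 20 for each, but the measures are not independent, since each array was centred on its autosomal median. The chromosome 6 median of tumour 3 was 0.36 and the chromosome 10 median of tumour 4 was 0.32. The chromosome Y median of tumour 4 was -0.52 over 141 probes with an interquartile range of 1.09. The chromosome 2 median of tumour 3 was -0.032, and its medians of chromosomes 1 and 3 were also the lowest of the 4, at -0.046 and -0.066. Centring on the mode moved its chromosome 6 median from 0.357 to 0.386, so the low chromosome 2 value may reflect the centring. Against the mean of the 4, and assuming that a lone tumour varies like them, limma called 556 bins for the Hdac1L/L tumour (1 higher and 17 lower without tumour 1, 1 and 15 without tumour 2) and 22 bins for the Hdac1L/+;Hdac2L/L tumour (0 without tumour 1 and 0 without tumour 2, with 492 and 518 bins at an unadjusted p under 0.05).

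The direction of the ratio on slide 1 is the first pattern weighed. If the dyes of the labels held there, losses shared by the arrays of slides 2 and 3 should appear as gains on slide 1. Of 15 probes below -0.5 on all 4 arrays of slides 2 and 3, on chromosomes 6, 13 and 14, 13 were below 0 on both slide 1 arrays (86.7%) and 0 were above 0 on both. Of 306 probes above 0.5 on those 4 arrays, all on chromosome 15, 278 were above 0 on both slide 1 arrays. Both counts argue against turned ratios on slide 1, provided that the tumours share these changes, which lie on only 4 chromosomes, and no biological explanation was tested.

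The block-wise scatter on the arrays of the Hdac1L/+;Hdac2L/L tumour and tumour 4 is the second pattern. Noise of each array on its own would make different probes deviate, but in the 22 windows noisy on both arrays absolute deviations correlated at 0.66 across probes, which are not independent replicates (interval over windows 0.62 to 0.70, against at most 0.06 with probes shuffled within windows). A candidate explanation is tumour and tail DNA of different make-up in the mixed strain, which would make the same probes deviate on both arrays, as they did. In these 22 windows, 323 probes deviated by more than 0.5 on both arrays, against 53 if the arrays were independent. Of these probes, 72.45% had opposite signs in the likely direction of slide 1. That the same single probes deviated argues against copy number changes that arose separately in the 2 tumours, for these windows only. For the other noisy windows copy number change in the tumour stays open. There the median interquartile range of called segments cannot decide. It was at least 3.21 times the noise SD on both arrays, but also 2.76 times in tumour 3 without such blocks. Loss of heterozygosity against matched tail DNA stays open too, because probes too high for it, at least 8.6 times as frequent in noisy as in quiet windows, were counted in windows chosen by their scatter, and the Hdac1L/L array without blocks gave 10.7 from 2 probes.

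The low gain of chromosome 11 in the Hdac1L/+;Hdac2L/L tumour is the third pattern. Correction for the GC content of bins kept 122% of its median, so GC content is not the whole cause, and the other slide 1 array lay 0.089 lower, which argues against an equal effect on both slide 1 arrays as the whole cause. The interval of 0.07 to 0.11 covers spread over bins and not between arrays, for which the SD of the chromosome 11 median in the 4 tumours was 0.0097. If chromosome 15 stands for 1 extra copy in every tumour cell, which was not tested, its level can be set against that of chromosome 11. The chromosome 11 level, 42.2% of that of chromosome 15 on the same array, then argues against an extra copy in every tumour cell. After GC correction the medians were 0.189 for chromosome 11 and 0.38 for chromosome 15. Part of the level may be technical, since chromosome 11 was between 0.04 and 0.07 in the other 5 tumours, and a gain in some of the tumour cells and the genotype itself stay open as untested.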

How the results depend on the processing

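Slide 1 ratios turned, uncorrected ratios, bins corrected for GC, joined segments and counts without the 2 arrays with block-wise scatter were tried only after seeing the data; the causes of the changes below were not tested unless stated. Among alternative values of main results, 144 kept their call or stayed within the limits set for a change, 50 moved beyond them and 2 newly passed a test. Chromosome 15 was the autosome gained in most tumours under every setting run, in 5 of 5 when 1 of the 4 tumours was left out, and its mean over the 4 ranged from 0.37 to 0.39 when each was left out. Each ratio already pairs a tumour with the tail DNA on its own array. Pairing tumours across genotype groups was not possible, because the labels carry no replicate numbers. The ratios at Hdac1 and Hdac2 were not run, for want of an annotation of the build. The authors' segments covered 5 arrays.

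Whole-chromosome losses rose from 0 to 1 with the mean over all probes (chromosome 19 of the Hdac1L/L tumour) and to 3 with slide 1 ratios turned, where chromosome 11 of the Hdac1L/+;Hdac2L/L tumour was at -0.154. Gains fell to 5 without the 2 arrays with block-wise scatter, which leaves 4 arrays. Gained and lost focal segments, 466 and 303, became 228 and 147 with a split statistic above 8, 157 and 76 with the authors' segments, and 225 and 67 without the 2 arrays. Losses became 182 with at least 10 probes and 134 with uncorrected ratios, and gains 184 with joined segments. Shared windows exceeded shifted calls with the authors' segments (1129 windows, permutation p = 0.033) and with joined segments (226 windows, permutation p = 0.01). They ranged from 1127 to 1216 when 1 tumour was left out.

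The chromosome 6 loss of the 4 tumours was -0.50 with 10 kb added on either side, -0.47 with 50 kb, -0.51 as a mean of probes and -0.63 minus its flanks; it ranged from -0.54 to -0.53 when 1 tumour was left out, and the chromosome 14 loss from -1.71 to -1.19.

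For the 4 tumours against 0, higher bins ranged from 249 to 648 and lower bins from 425 to 729 when 1 tumour was left out. Uncorrected ratios gave 287 higher bins and GC correction 318 lower ones. With the slide as a random block (estimated correlation 0.23) the counts were 412 and 538. For the Hdac1L/L tumour, higher bins ranged from 1 to 375 and lower ones from 15 to 400 when 1 of the 4 was left out, and uncorrected ratios gave 155 and 132. For the Hdac1L/+;Hdac2L/L tumour, higher bins ranged from 0 to 133 and lower ones from 0 to 190. Its higher and lower bins were 3 and 8 with bins of 0.5 Mb, 79 and 94 with bin means, 6 and 5 with no centring, 169 and 207 with slide 1 turned, and 0 and 1 with uncorrected ratios. Its higher bins were 12 of 504 with bins of 5 Mb and 36 with GC correction, and its lower bins were 5 with centring on the mode and 5 with at least 20 probes per bin. Signal over background was not given by the files, so the noise SD of 0.11 to 0.20 was used to judge precision.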

Other observations

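The values here were chosen after they had been seen, and none was tested. Single probes of chromosome 13 were far below 0 on all 6 arrays as EXP over REF. With the sign turned, the Hdac1L/L and Hdac1L/+;Hdac2L/L tumours would be above 0 there. The probe at 19286933 ranged from -3.18 to -0.78 and the probe at 19418296 from -2.14 to -0.66, while the probes next to them lay between -0.23 and 0.23. The segmentation, which needs 5 probes, could not call them. These 2 probes were among 10 autosomal probes below -0.5 on all 6 arrays, the others being 5 on chromosome 14 and 3 on chromosome 6. The T cell receptor gamma locus is known to lie on mouse chromosome 13, but the probes were not placed against an annotation of this build.

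On the sex chromosomes, tumour 1 had a median of -0.12 over 8581 probes of chromosome X, against -0.05 to -0.003 in the other tumours. Tumour 4 had a loss from 163660518 to 166633137 on chromosome X, at -0.59 over 156 probes. On the arrays with block-wise scatter, 26 called segments covered each other by at least 50%, 15 with opposite and 11 with the same sign, and the other way round with the slide 1 ratios turned. On chromosome 2, for example, the segment that starts at 174816633 was at -0.49 in the Hdac1L/+;Hdac2L/L tumour (0.49 with the sign turned) and at 0.23 in tumour 4.

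Across 1 Mb bins without chromosome 15, the arrays of slide 2 correlated at 0.46 to 0.72 with each other and at 0.30 to 0.46 with tumour 4 on slide 3, and the slide 1 pair at 0.31. Slide 1 arrays and the others correlated at -0.06 to 0.03. These values are across bins, which are not independent replicates.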
